A study of Lilium davidii var. unicolor with 6 samples.

How the data were processed

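RNA sequencing libraries from 6 samples of lily bulb scales, 3 watered with distilled water and 3 with methane-rich water (MRW), were compared. Per the labels' protocols, scales were soaked for 3 h in distilled water or MRW, set in moist perlite and vermiculite, watered every 3 days, and frozen 10 days after treatment began. Libraries followed standard Illumina protocols. The labels give biological replicates without saying how culture, extraction or sequencing were batched, so no batch could be examined.

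The deposited table holds 14140 rows, each a full-length transcript identifier with a length in bases, and for each sample a column of estimated counts and a column of FPKM. The identifiers have the form used for PacBio Iso-Seq transcripts, in which the number after f is the number of full-length reads and the last number a length. The submitters' processing notes name Subread, with no role or version. The series' design text names the soybean genome as the alignment target, whereas the rows carry transcript identifiers and no soybean gene names, so what the reads were aligned to is uncertain. The program that estimated the counts, its settings and whether strand was used are not given in the sources used here. The estimated counts deposited by the authors are not normalized, and 56.0% to 57.8% of the values per library are whole within 0.005. The FPKM values were deposited by the authors as well. Regressing the ratio of count to FPKM on length gave library totals within 0.00117% of the column totals, and a length shortened by 250 to 259 bases. FPKM was therefore scaled to the sum of the estimated counts in the table and to an effective length. FPKM was 0 beside at least 1 count in 2 to 6 rows per library. Every row has an identifier, and no per-sample column was left unused.

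Estimated counts were rounded to whole numbers. Transcripts with too few counts were removed with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13331 and removed 809. Libraries were scaled by TMM (factors 0.942 to 1.031), and MRW was tested against control with edgeR 4.0.16 (glmQLFit and glmQLFTest, R 4.3.3) with treatment as the only term and Benjamini-Hochberg adjustment over all tested transcripts at 0.05. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. The common biological coefficient of variation was 0.154. On counts simulated from these 13331 transcripts, with 200 changed, the same test recovered 52.2% of 1.5-fold, 82.1% of 2-fold and 100% of 4-fold changes, and 6.02% of its calls were false. The simulated counts were drawn independently for each transcript, with no length trend between libraries and no reads shared between sequences. The 6.02% is therefore no estimate of the false calls in the data. Single library measures were compared by exact two-sided permutation tests, whose smallest p with 3 against 3 is 0.1. Counts of 0 were given a floor of 3 counts per library, which covers counting error only. Of the transcripts called at least 2-fold changed, 52 had 0 counts in all libraries of one group, and all 52 remained at least 2-fold against that floor. The filter kept such transcripts only with about 10 counts or more in each library of the other group. That outcome was therefore fixed in advance and lends no support. Replicate libraries of one group differed by 8.2 to 27.3 times the chi-square expected from sampling alone, so none was counted as a repeat of another.

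The test, samples, alternatives and the rule for named items were fixed before the data were examined. For rows with identifiers only, the rule takes the 2 largest rises and 2 largest falls by fitted log2 fold change among called transcripts with non-overlapping groups and a mean of at least 1 CPM. The 21 gene lists fixed at that time (hormones, starch and sucrose, cell cycle, cell wall and others) rest on gene names or descriptions, so 0 of them could be matched and no list was tested. The classes of length, abundance, whole counts and full-length reads and the present or absent set were chosen after the data were seen.

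The alternatives tried were RLE (DESeq2) and upper quartile factors, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), no filter, a stricter filter of 10 counts, the replicate number as a block, a 2-fold threshold, and leaving out each library. Chosen after seeing the data were library totals as the only scaling, removal of a loess trend on log2 length (span 0.3) from each library, transcripts with whole counts alone, and limma on log2(FPKM + 1). The labels use the numbers 1 to 3 in both groups without saying what they share. Libraries with the same number had correlations of -0.068 to -0.014 in their deviations from the group means, so they were not treated as pairs.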

Results

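Transcript abundance was measured by paired-end RNA sequencing in bulb scales of the Lanzhou lily, Lilium davidii var. unicolor, an edible lily that can be multiplied by rooting detached scales. The scales were sampled 10 days after cutting. One group had been watered with distilled water (control, n = 3) and the other with methane-rich water, that is, water charged with methane gas (MRW, 100% strength, n = 3). The labels describe 3 biological replicates of 40 scales each, and the comparison asks which transcripts of the scale differ with MRW during the period in which bulblets form. The control libraries held 22854766, 20988773 and 28031469 estimated counts and the MRW libraries 25031246, 22154105 and 27073860 (exact two-sided permutation test of the means, p = 0.8, smallest possible p = 0.1). The features were 14140 full-length transcript sequences, each given by an identifier and a length, and not by a gene name. Several of these sequences can come from 1 gene. Genomic positions, gene functions and pathways are therefore not reported here.

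At least 1 count was found for 13529 ± 26.3 transcripts in control libraries and for 13447 ± 16.5 in MRW libraries (SD, n = 3 each). The 3 control values all lay above the 3 MRW values, and the exact two-sided permutation test gave p = 0.1, the smallest this design allows (0.183 after Benjamini-Hochberg adjustment over the 11 library measures compared). The 11 include count shares of transcripts called on these same libraries, whose permutation p of 0.1 was set by that choice. Their presence makes this adjusted value too small. The most abundant transcript took 3.89% ± 0.252 of the counts in control and 4.01% ± 0.207 in MRW (SD, n = 3), and the 100 most abundant took 31.6% ± 1.11 and 32.0% ± 0.486. These shares differed by less than the spread between replicates.

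The 2 treatments gave separate expression profiles. Correlations of log2 CPM between libraries of the same group ranged from 0.956 to 0.971, and those between libraries of different groups from 0.896 to 0.911 (Pearson, across 13331 transcripts, which are not independent replicates). The first principal component carried 60.4% of the variance and parted the treatments. The second carried 12.4% and set control replicate 2 apart from the other control libraries. The mean distance between groups exceeded that within groups by 0.0604 (1 minus Pearson's r), more than in any of the other splits of the 6 libraries, and the exact permutation p of 0.1 was the smallest possible with 10 splits.

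**Figure D1:**
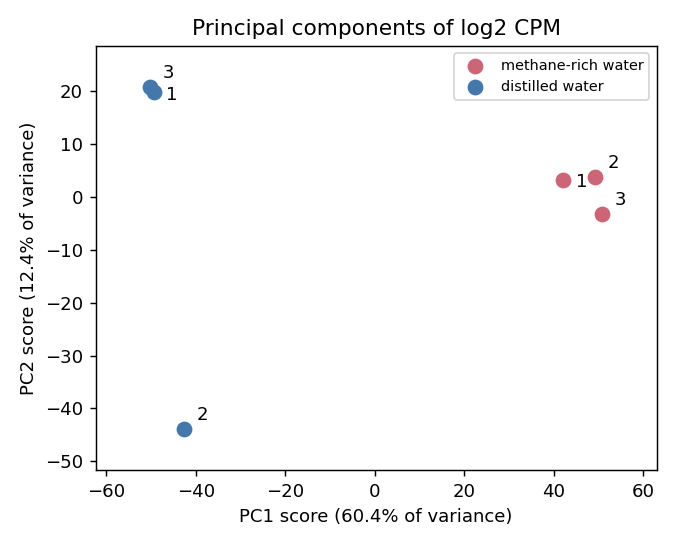
Scores of the 6 libraries on the first principal components of log2 CPM (x axis, component 1; y axis, component 2, both unitless), coloured by treatment and numbered by replicate. Control libraries lie between -50.2 and -42.6 on component 1 and MRW libraries between 42.1 and 50.9, and control replicate 2 lies at -43.9 on component 2.

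Scales given MRW differed from control scales in 2334 of the 13331 transcripts tested (17.5%). Of these, 1584 were lower and 750 higher in MRW (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The larger changes went almost wholly downwards. At least 2-fold lower in MRW were 905 transcripts against 65 at least 2-fold higher, and at least 4-fold lower were 449 against 15 higher. The transcripts at least 2-fold lower had together taken 4.38% ± 0.0699 of all counts in control scales and took 1.22% ± 0.0929 in MRW scales (SD, n = 3). Those at least 2-fold higher took 0.0607% ± 0.00153 in control and 0.168% ± 0.00611 in MRW. Both sets were chosen on these libraries, so their shares describe the size of the change and are not independent evidence for it.

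Every one of the 2334 called transcripts had its 3 MRW values wholly above or wholly below its 3 control values. A low p with 3 libraries per group favours such separation, so for the called transcripts it is not independent evidence. Such separation was seen in 4892 transcripts (36.7%), where chance would give 10%. The median log2 fold change of the transcripts tested was 0.02, so the calls are in effect relative to the typical transcript. The balance of small changes depended on the scaling between libraries. With upper quartile factors, which moved the median to 0.14, the calls numbered 2003 higher (59.3%) and 1375 lower, and with library totals alone 1017 higher (42.4%) and 1384 lower. The number of higher transcripts also moved by over 1.5 times when a library was left out. It was 372, 1287 and 462 without control replicates 1, 2 and 3, and 494, 322 and 392 without MRW replicates 1, 2 and 3.

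**Figure D2:**
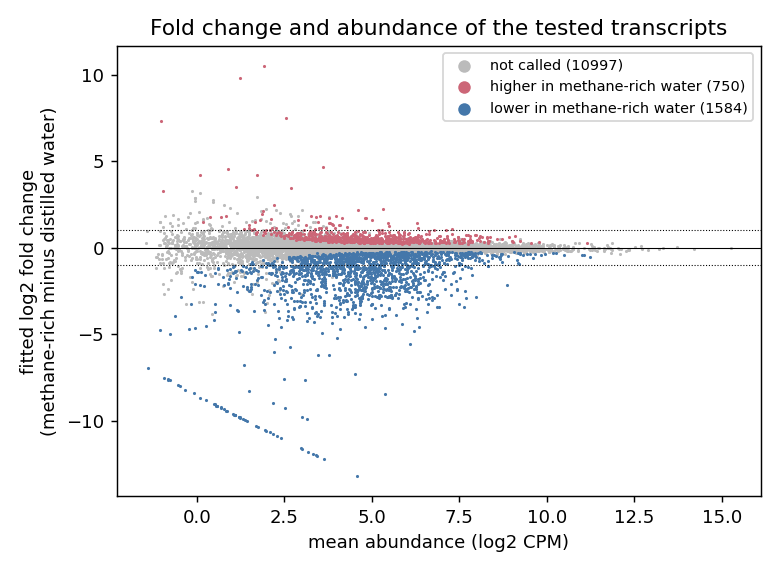
Fitted log2 fold change, MRW minus control (y axis), against mean abundance in log2 CPM (x axis) for the 13331 tested transcripts. Colours mark the 750 called higher, the 1584 called lower and the rest, and dotted lines mark 2-fold. Points on the lower left diagonal have no counts in any MRW library. Their fold is set by a small constant in the edgeR fit, not by the prior count of 2 used for log2 CPM.

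The direction of the calls differed between classes of transcript length. Among the 3771 tested transcripts of up to 1000 bases, 704 were lower and 120 higher in MRW. Among the 4992 of over 1000 and up to 2000 bases, 596 were lower and 210 higher, and among the 4568 over 2000 bases, 284 were lower and 420 higher. The median log2 fold change of the transcripts over 2000 bases was 0.19, and it stayed between 0.12 (without control replicate 3) and 0.26 (without control replicate 2) with each library left out. The majority of calls over 2000 bases, in contrast, turned when any library but control replicate 2 was left out. The class then held 188 higher and 251 lower without control replicate 1, and 201 and 294 without control replicate 3. It held 270 and 276 without MRW replicate 1, 147 and 246 without MRW replicate 2, and 198 and 257 without MRW replicate 3. Without control replicate 2 it held 877 higher and 280 lower. With all libraries, 36 of the 420 higher calls in the class were at least 2-fold, against 176 of the 284 lower ones. Small changes are lost first when fewer libraries are tested. For the fits in which the majority turned, lost power and dependence on single libraries therefore cannot be told apart. Lost power would not give the rise from 420 to 877 higher without control replicate 2. In the middle class the majority turned with upper quartile factors, to 675 higher and 511 lower. In the shortest class lower transcripts outnumbered higher ones under every scaling and with any library left out. Among these fits they did so least with upper quartile factors, by 607 to 252, and with a library left out least without control replicate 3, by 563 to 126. Without control replicate 2 the numbers were 1152 and 107. With a smooth length trend removed from each library they were 696 and 335. In the fit with all libraries, lower transcripts made up 18.7% of the shortest class against 9.21% of longer transcripts, and higher transcripts made up 9.19% of the longest class against 3.77% of shorter ones. The median length was 1084 bases for lower and 2158 bases for higher transcripts. Across transcripts, log2 fold change and length had a Spearman rho of 0.412. It was 0.263 without control replicate 3, 0.512 without control replicate 2, and 0.369 to 0.398 with one of the other libraries left out. Pearson's r with log2 length was 0.13. Transcripts are not independent replicates, so these shares and correlations carry no p.

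The length difference was not shared evenly by the libraries. The median log2 deviation of transcripts over 2000 bases minus that of transcripts up to 1000 bases was -0.21, 0.14 and -0.36 in control replicates 1, 2 and 3, and 0.15, 0.17 and 0.13 in MRW replicates 1, 2 and 3. The group means of -0.14 ± 0.26 and 0.15 ± 0.02 (SD, n = 3) gave p = 0.2 in an exact two-sided permutation test (adjusted 0.314, smallest possible p = 0.1). The adjusted value is too small, since the measures adjusted over include shares of transcripts called on these libraries. When that length trend was removed, 182 of the transcripts over 2000 bases were called higher and 428 lower. The median log2 fold change of that class fell from 0.19 to 0.01, since the removal brings it near 0 by construction. Transcripts at least 2-fold lower outnumbered those at least 2-fold higher in every length class with and without that step, by 389 to 15, 340 to 14 and 176 to 36 from short to long without it, and by 353 to 23, 335 to 13 and 206 to 28 with it.

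**Figure D3:**
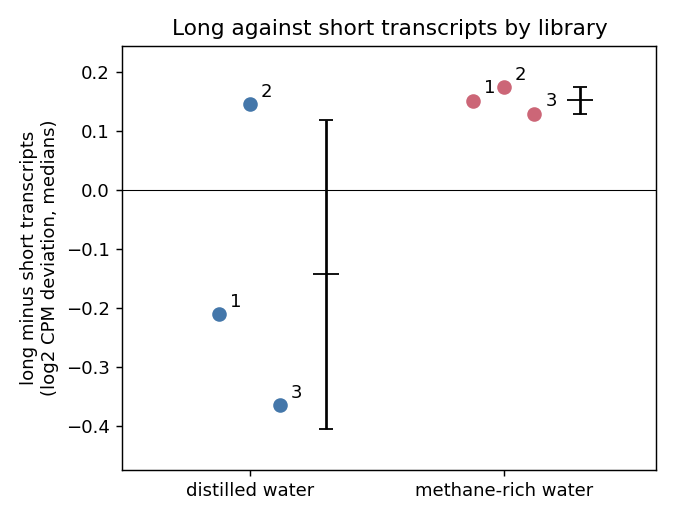
Median log2 CPM deviation of transcripts over 2000 bases minus that of transcripts up to 1000 bases (y axis) for each library by treatment (x axis). Points are libraries numbered by replicate, and black bars are the group mean ± SD (n = 3). Control replicate 2, at 0.14, lies with the MRW libraries and apart from the other control libraries.

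The excess of strong decreases was found at every abundance. Of transcripts with a mean of up to 10 CPM, 298 were at least 2-fold lower and 33 at least 2-fold higher. The numbers were 445 and 28 between 10 and 50 CPM, and 162 and 4 above 50 CPM. Deposited counts were whole in all 6 libraries for 6952 of the tested transcripts and carried decimals for 6379, as arises where a program shares reads out between similar sequences. At least 2-fold lower were 394 transcripts with whole counts (5.67%) and 511 with decimals (8.01%). At least 2-fold higher were 16 with whole counts and 49 with decimals.

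A small set behaved as present or absent. In 57 transcripts the 3 MRW libraries held at most 3 counts in all while the control libraries held at least 30, with a median of 314 counts and a range of 43 to 3250. The reverse was seen in 3 transcripts. All of these were called by the test. Counts with decimals were found in all 57 of the former and in 2 of the latter.

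The transcripts with the largest fitted changes belonged to this set, and the counts of all 4 named here carried decimals. Transcript transcript_HQ_Ld3_vu_transcript166/f2p0/7366, a sequence of 7358 bases, had 1145, 1298 and 807 counts in control replicates 1, 2 and 3 and 0 in each MRW library. Its control level was 47.8 ± 15.4 CPM (SD, n = 3), or 6.61 ± 2.36 FPKM in the deposited values. Against a floor of 3 counts in each MRW library its group mean was at least 403-fold lower (edgeR adjusted p = 4.8e-05). Transcript transcript_HQ_Ld3_vu_transcript15074/f2p0/1703, of 1703 bases, had 557, 443 and 735 counts in control and 0 in each MRW library. At 24.7 ± 3.75 CPM in control (SD, n = 3), its group mean was at least 208-fold lower in MRW on the same floor (edgeR adjusted p = 5.5e-06).

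In the other direction, transcript_HQ_Ld3_vu_transcript18662/f2p0/1319, of 1319 bases, had 0 counts in each control library and 258, 95 and 213 in MRW replicates 1, 2 and 3. At 7.28 ± 2.93 CPM (SD, n = 3) its group mean was at least 55.9-fold higher in MRW, against a floor of 3 counts in each control library (edgeR adjusted p = 0.000244). Transcript transcript_HQ_Ld3_vu_transcript5773/f2p0/2796, of 2797 bases, had 0 counts in each control library and between 94 and 124 in the MRW libraries. At 4.54 ± 1.06 CPM (SD, n = 3) its group mean was at least 34.8-fold higher on that floor (edgeR adjusted p = 0.000131).

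**Figure D4:**
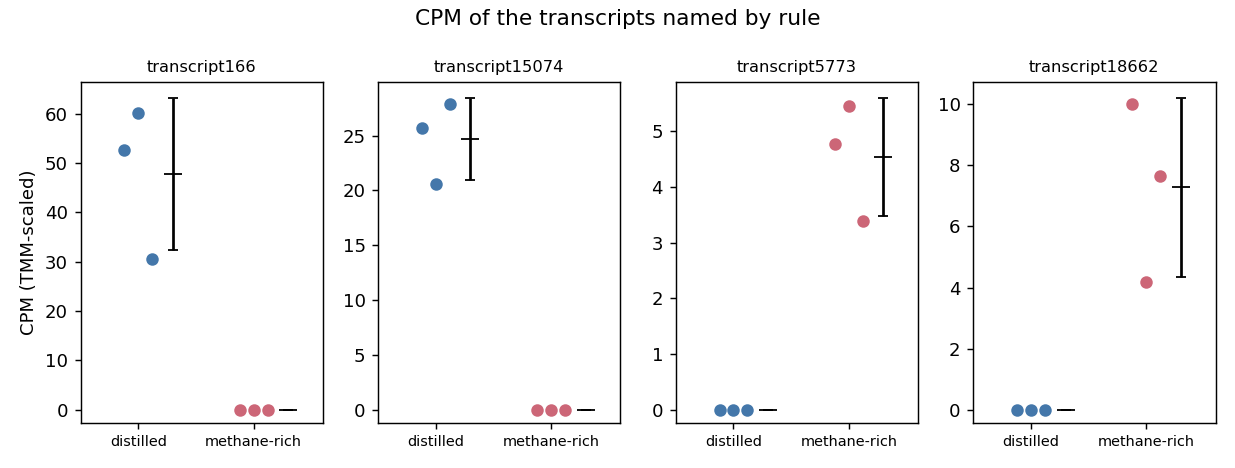
Abundance in TMM-scaled CPM (y axis, a separate scale in each panel) of the 4 named transcripts by treatment (x axis). Points are libraries and black bars the group mean ± SD (n = 3). The 2 left panels reach 60.2 and 27.9 CPM in control and 0 in MRW, and the 2 right panels reach 5.46 and 10.0 CPM in MRW and 0 in control.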

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

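The 2-fold counts under each alternative, and library totals, length trend, whole counts and FPKM as alternatives, were chosen after seeing the data; the others were planned. Of the alternative values of the 5 counts and of the distance between groups, 73 stayed within 1.5 times (or within 1 SD) and 17 did not. Leaving aside the 2-fold threshold and whole counts alone, the number changed (2334) ranged from 1603 without MRW replicate 2 to 3378 with upper quartile factors. It was 2662 with DESeq2 and 2427 with limma-voom, of which 2295 and 2299 were among the 2334, all in the same direction. Upper quartile factors gave 2003 higher and 104 at least 2-fold higher; the cause was not tested beyond the median shift. Requiring a 2-fold change left 970 changed, 65 higher and 905 lower, by construction. Whole counts alone gave 1595 changed, 641 higher and 954 lower, with 401 at least 2-fold lower and 17 at least 2-fold higher, from 6952 transcripts tested. On the same 6952 the main fit called 364 higher and 750 lower, with 394 at least 2-fold lower and 16 at least 2-fold higher. Whole counts alone thus gave more calls on these transcripts and nearly the same number at 2-fold. Its values among the 17 were set against the main fit on 13331 transcripts, so they show no loss of calls. Leaving out one library gave 322 to 1287 higher and 1603 to 3354 changed; the high value came without control replicate 2 and the low one without MRW replicate 2. With the replicate block 1844 were changed, 468 of them higher; same-numbered libraries did not deviate together, and 0 of the 6 libraries correlated best with its own number. The distance between groups was 0.328 over the 500 most variable transcripts, which were picked for their variance, and 0.0537 with Spearman's rho; the cause was not tested. The count at least 2-fold lower lay between 754 and 921 in all alternatives but whole counts, which tested only 6952 transcripts. The 4 named transcripts kept their direction and call in all 16 alternatives that tested them; the fit on whole counts did not include them. In the simulation with 3 libraries per group, 52.2% of 1.5-fold changes were recovered, so small changes may be undercounted. This share cannot be carried over to the data as a value. The simulation held 200 changed transcripts and gave 166 calls, against 2334 calls in the data. The p needed to pass the adjustment depends on the number of calls. The list tests were not run, and pseudocounts were planned only for a table without counts.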

Other observations

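All tests below were chosen after the patterns were seen. Only those of the scaling between libraries and of length among transcripts over 1000 bases were written down before their own values were computed. All interpretations are hypotheses, and the methane treatment itself remains an open and untested explanation for each pattern.

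Strong decreases outnumbered strong increases by 905 to 65. The tables argue against the scaling between libraries as the cause, since the ratio of lower to higher was at least 7.88 under TMM, RLE, upper quartile factors and library totals. A reference that holds more of the transcripts used in control scales stays open. Among transcripts changed 2- to 4-fold with a mean of at least 50 CPM, 87 were lower and 4 higher. Of those 87, 21 (24.1%) rest on 2 full-length reads and could have been missed at a lower level. With 2 full-length reads, 440 transcripts were at least 2-fold lower and 35 at least 2-fold higher. The numbers were 406 and 25 with 3 to 10 reads, and 59 and 5 with over 10. The excess was thus not confined to transcripts with few reads. In such a reference the number of reads would itself follow the control level, so these classes cannot decide. RNA from another cell type or an organism on the control scales may also contribute. The lower transcripts took a similar share of every control library, 4.31%, 4.39% and 4.45%, and their median log2 deviations from the control mean spanned 0.129. They were called on these same libraries by a test that favours a small spread within groups, so this evenness is partly built in. An even amount of such RNA would also give it, as would shared regulation. Without names or sequences the explanations cannot be told apart.

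Fold change rose with length. A recovery of long transcripts that varies from library to library is a candidate explanation, since the long-minus-short value spanned 0.51 among control libraries, 1.73 times the difference between groups of 0.295. An effect of fragment length on very short transcripts alone is argued against, since rho was 0.387 among transcripts over 1000 bases. Of the 750 higher transcripts 420 were over 2000 bases. Removing a length trend from each library brings the medians of the length classes near 0 by construction, whatever the cause. The fall of that class's median log2 fold change from 0.19 to 0.01 is therefore no evidence for or against uneven recovery. Nor is the shift of its calls from 420 higher and 284 lower to 182 and 428. Leaving out single libraries turned the calls in most cases but kept the median at 0.12 or above. Removing the trend left 894 at least 2-fold lower and 64 at least 2-fold higher.

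The 57 transcripts absent or nearly absent in MRW all carried counts with decimals (100%), against 47.5% of 13230 others with at least 30 control counts (Fisher's exact test, two-sided, p = 4.267e-19, which treats transcripts as independent although similar sequences are not). This is consistent with reads shared among near-identical sequences being assigned to another copy in the MRW libraries, and a real change of isoform or allele would look alike in this table. A lower depth is argued against, since the MRW libraries held 1.033 times the counts of the control libraries. Their median length was 2798 bases, against 1084 for all lower transcripts. Sequences of the 57 and of their nearest relatives would be the first thing to examine.

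The real split of the 6 libraries gave 2334 changed, 750 higher and 1584 lower transcripts, and the highest of the other splits gave 0 of each with edgeR's quasi-likelihood test (at most 687 at an unadjusted p under 0.05, against 4129). For each count 1 of the 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Every other split places libraries of both treatments in each group. A treatment difference then widens the spread within groups and lowers the calls. The 0 calls are therefore no estimate of the false calls in the real split.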
